A study of Mus musculus with 8 samples.

How the data were processed

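RNA from mouse primary hepatocytes infected with Ad-LacZ or Ad-Pink1 was sequenced 48 h after infection, with 4 libraries per group. Per the labels' protocols, RNA was purified on spin columns and 2 ug of total RNA went into a stranded, poly(A)-selecting mRNA kit. The authors deposited a single table of 23440 genes for the whole series. Per the file headers it holds total counts per gene from trimmed first reads, and per the submitters' processing notes the genome build was mm10. The aligner, the annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. The deposited counts are whole numbers with no normalization. The same table holds the authors' own log2 fold changes and adjusted p-values, which are used here only where named as theirs, and 24 columns of RPKM, TPM and CPM values, which were not used. Columns were matched to samples by name through the labels.

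Genes with too few counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 13095 of 23440 genes. Library sizes were scaled with TMM factors. Each gene was tested with edgeR's quasi-likelihood test with robust dispersion estimation on all 8 libraries, with group as the single factor, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. For large changes with few reads in either group this value is too small and can fall below counting error. CPM values use TMM-scaled library sizes, and means and SDs are over the 4 libraries of a group.

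A total of 40 gene lists, covering liver functions, stress responses, mitochondrial pathways and markers of other cell types, was fixed before the data were examined, as were the tests and the rule for naming genes. Older symbols in the table were matched to the listed genes. The list test was camera of limma 3.58.1 on log-CPM (prior count 2) with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 37 lists with at least 5 tested members. The same test with a correlation estimated from the data, and fry, were run as alternatives. With an estimated correlation, camera takes its degrees of freedom from the 8 libraries, and with a preset one from the number of genes. Fewer degrees of freedom make small p-values larger whatever the correlation. Counts of called members are given over all genes tested. The named genes were Pink1, the 8 genes with the largest rise and the 8 with the largest fall, the 5 higher and 5 lower genes with the smallest adjusted p among the rest, and up to 4 members with the smallest adjusted p of each list that passed camera or had at least 25% of its tested members called. The first groups were limited to called genes whose groups did not overlap, with a mean of at least 2 CPM in the higher group and no predicted-gene symbol. The text gives some of the up to 4 members per list, and some genes the rule takes are not reported here.

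The tests were checked on simulated counts for Ad-Pink1 against Ad-LacZ. Counts were drawn from the Ad-LacZ means, the library sizes without Pink1 and the fitted dispersion trend. Far fewer genes were changed than were called in the real data, so recovery and false calls describe this setting only. In a table of 12499 tested genes, edgeR recovered 68% of 50 genes changed 1.2-fold, 90% at 1.5-fold, 100% at 2-fold and 98% at 4-fold, and 7 of 12301 unchanged genes were called. In 40 simulated lists camera found the list of 30 genes moved by 0.5 on the log2 scale and called 1 of the 39 others. The simulated genes were drawn independently, so this does not show how often camera calls lists of correlated genes falsely.

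Before averaging, replicates were compared over genes with at least 10 reads. Each pair within a group differed by more than sampling noise, with a chi-square per gene of at least 1.59, so no library was treated as a second copy of another. This does not show that the libraries came from separate animals or cultures. Alternatives were other scalings (RLE, upper-quartile, none), Pink1 left out of the library sizes, no filter or at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, dispersions estimated without the robust option, each library left out, and stricter thresholds. A correction for GC content and transcript length was added after the data were seen, with values for 99.4% of the tested genes from the longest transcript of each gene in GENCODE vM21. For DESeq2 the list test was the pre-ranked form of camera, run on DESeq2's own test statistics instead of log-CPM, with the same preset correlation. R 4.3.3 was used.

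Some values carry a limit from counting. Members of families with near-identical copies (Serpina1, Mup, Ugt2b, Cyp2c, Gsta and H2-Q genes) are uncertain individually. Since the strand setting is not stated, genes that overlap a gene on the other strand are uncertain too. Among named genes with an overlapping neighbour that has reads these are Fosl1 (Ccdc85b), Stab1 (Nt5dc2), Atf5 (Nup62), Cp (Hps3), Shmt2 (Ndufa4l2), Tcfl5 (Col9a3), Pcx (Lrfn4) and Trap1 (Dnase1). The viral dose and the infected share of cells are not given in the sources used here.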

Results

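The transcriptome of mouse primary hepatocytes, wild type and of the C57Bl6/J strain, was measured 48 h after infection with an adenovirus. Cells received either Ad-LacZ, which carries the bacterial reporter LacZ and served as the control, or Ad-Pink1. Pink1 encodes a mitochondrial serine/threonine kinase that builds up on damaged mitochondria and recruits the ubiquitin ligase Parkin. Each group had 4 libraries, made from 2 ug of total RNA with a stranded mRNA kit. Total counts ran from 16204467 to 18270933 in the Ad-LacZ libraries and from 17690330 to 21579567 in the Ad-Pink1 libraries. At these depths 3 reads corresponded to between 0.143 and 0.18 CPM, the counts scaled to library size. The labels do not say whether the libraries came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. That spread was small, with a common coefficient of variation of 3.49% beyond counting error.

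Of the genes in the table Pink1 itself had the most reads in every Ad-Pink1 library. It averaged 81.1 ± 12 CPM (SD, n = 4) in Ad-LacZ and 115500 ± 2250 CPM (SD, n = 4) in Ad-Pink1, a log2 fold change of 10.48 ± 0.12 (SE; edgeR quasi-likelihood test, adjusted p = 9.35e-11). Its share of all counts was 0.00832% ± 0.00123 (SD, n = 4) in Ad-LacZ and 11.2% ± 0.208 (SD, n = 4) in Ad-Pink1. The Wilson 95% interval was 0.00689% to 0.00769% in Ad-LacZ replicate 3, where the share was lowest, and 11.44% to 11.47% in Ad-Pink1 replicate 1, where it was highest. Intervals and count floors cover counting error only, since the reads carry no molecular identifiers. In the deposited table, on genome build mm10, Pink1 lies on the minus strand of chromosome 4 from 138313410 to 138326296. Ddost, its neighbour on the plus strand, ends at 138312611 and does not overlap it. Reads from the vector and from the endogenous gene are counted together, and the labels do not give the species or form of the transgene. In the authors' deposited table the Pink1 log2 fold change was 10.46.

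**Figure D1:**
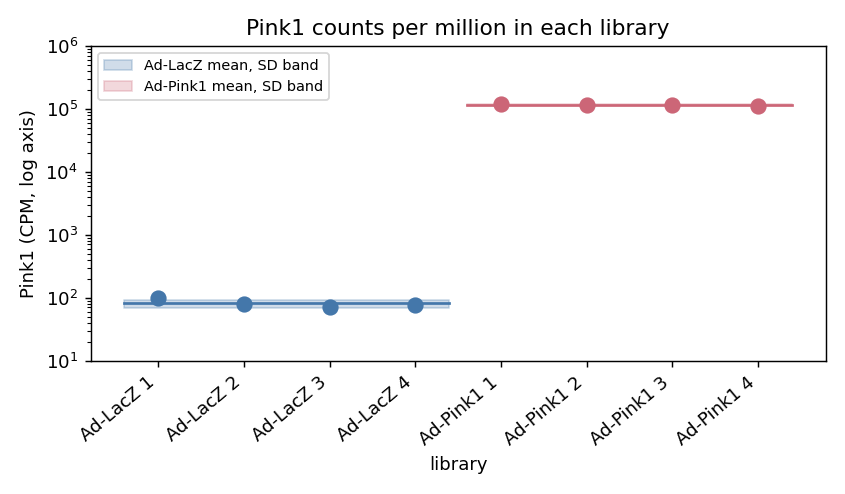
Pink1 in CPM (log axis) in each of the 8 libraries, with points for libraries, lines for group means and bands for the SD. The 4 Ad-LacZ libraries averaged 81.1 CPM and the 4 Ad-Pink1 libraries 115500 CPM, with no overlap.

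The comparison asks how hepatocyte transcription responds to Pink1 over-expression. In cells given Ad-Pink1, transcripts were higher for 32 of 32 tested cell cycle genes, 25 of 30 integrated stress response genes and 19 of 26 glycolysis genes and HIF1 targets. They were lower for 29 of 34 interferon-stimulated genes, 25 of 30 hepatocyte identity genes and 24 of 30 genes of fatty acid oxidation. These 6 lists passed camera, a test of a list against all other genes, but not when the correlation between genes was estimated from the data (adjusted p = 0.133 to 0.428 with an estimated correlation). Of 13095 genes tested, 4896 were higher in Ad-Pink1, 5005 were lower and 3194 were not called by edgeR at an adjusted p under 0.05. Many of the changes were small: 2439 of the called genes, 24.6%, differed by less than 1.2-fold, while 1042 rose and 592 fell at least 2-fold. The values of the groups did not overlap for 9025 genes, 68.9% of those tested, where chance gives 2.86%. The first principal component of log-CPM held 86.2% of the variance and separated the groups.

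Dntt, a template-independent DNA polymerase of developing lymphocytes, had the largest log2 fold change after Pink1 among the named genes that rose, at 6.67 ± 0.26 (SE). It had 5 reads over the 4 Ad-LacZ libraries and 600 over the 4 Ad-Pink1 libraries, a ratio of 112 with a 95% counting interval of 47.8 to 347. This interval is wider than the SE implies. The matrix protease gene Mmp3 went from 1.13 ± 0.106 to 39.3 ± 3.48 CPM (SD, n = 4 each), and Il11, which encodes a cytokine of the interleukin 6 family, from 0.297 ± 0.128 to 10.3 ± 0.88 CPM. Sult1e1, the estrogen sulfotransferase, rose by 4.98 ± 0.17 on the log2 scale, and Aldh1a3, a retinaldehyde dehydrogenase, by 4.37 ± 0.19. Tcfl5 rose by 4.16 ± 0.21 and the cadherin gene Fat2 by 4.15 ± 0.19. Of these 7 genes Tcfl5 had the largest edgeR adjusted p, 3.64e-15. With so few Ad-LacZ reads, the SEs in this paragraph understate counting error.

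The largest falls among the named genes included the sodium channel gene Scn7a, from 13.7 ± 0.8 to 1.00 ± 0.262 CPM (SD, n = 4 each), and the interferon-induced Ifit1, from 53.5 ± 15 to 5.53 ± 1.03 CPM. Serpina1b, which encodes an alpha-1-antitrypsin, dropped by 3.12 ± 0.04 (SE) on the log2 scale and Serpina1a dropped by 2.95 ± 0.04. Dsg1c, a desmoglein, dropped by 3.25 ± 0.20 and Zfyve28 dropped by 3.24 ± 0.16. Ldoc1l dropped by 2.94 ± 0.25 and Rcan2, a calcineurin regulator, dropped by 2.76 ± 0.16. For genes with few Ad-Pink1 reads, such as Ldoc1l (0.29 CPM) and Dsg1c (0.42 CPM), the SE understates counting error. Ifit1 had the largest edgeR adjusted p of these 8 genes, 4.29e-05. The Serpina1 genes are near-identical copies, so the split of reads among them is uncertain.

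Among the genes with the smallest adjusted p-values, Cp, which encodes the copper carrier ceruloplasmin, fell from 6913 ± 172 to 1535 ± 28.7 CPM (SD, n = 4 each), and Spp1, which encodes osteopontin, from 9352 ± 176 to 2389 ± 27.7 CPM. Osgin1, an oxidative stress response gene, dropped by 2.01 ± 0.03 (SE) on the log2 scale, Bicc1 dropped by 2.13 ± 0.04 and Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, dropped by 1.78 ± 0.03. The adenylyl cyclase gene Adcy1 rose from 11.6 ± 0.475 to 123.5 ± 2.18 CPM. Ccp110, which acts at centrioles, rose by 2.41 ± 0.04, the cyclin gene Ccnf by 2.37 ± 0.04 and Cd109 by 2.34 ± 0.04. Of these 9 genes Cd109 had the largest edgeR adjusted p, 1.42e-23.

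All 32 tested cell cycle genes were higher in Ad-Pink1, with a median log2 fold change of 1.16 (camera adjusted p = 3.65e-13, and adjusted p = 0.133 with an estimated correlation). The ribonucleotide reductase subunit gene Rrm2 rose by 1.97 ± 0.03 (SE) on the log2 scale and the cyclin E gene Ccne1 by 2.33 ± 0.04. The mitotic kinase genes Cdk1 and Aurka rose by 1.53 ± 0.03 and 1.67 ± 0.04. Among 20 tested p53 targets 13 were higher, 2 lower and 5 not called, with a median of 0.57 (camera adjusted p = 0.00292, and adjusted p = 0.138 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 1.27 ± 0.03 and Ccng1 by 0.78 ± 0.03. Gtse1, which is expressed in dividing cells, rose by 1.15 ± 0.03.

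Of 30 tested hepatocyte identity genes 25 were lower and 5 not called, with a median log2 fold change of -0.86 (camera adjusted p = 1.9e-08, and adjusted p = 0.241 with an estimated correlation). Besides Serpina1a and Serpina1b, the related Serpina1c dropped by 2.39 ± 0.04 (SE) and the major urinary protein gene Mup20, also one of a family of near-identical copies, dropped by 1.21 ± 0.03. Of 23 acute-phase protein genes 15 were lower, 6 higher and 2 not called, with a median of -0.97 (camera adjusted p = 0.0058, and adjusted p = 0.428 with an estimated correlation). Fga, a fibrinogen chain, fell from 219 ± 6.4 to 59.3 ± 5.07 CPM (SD, n = 4 each) and Lcn2, the iron-scavenging lipocalin, from 838 ± 25.3 to 315 ± 19.4 CPM. Of 25 drug metabolism genes 15 were lower, 6 higher and 4 not called (camera adjusted p = 0.0394, and adjusted p = 0.428 with an estimated correlation). The glucuronosyltransferase gene Ugt2b5 dropped by 1.68 ± 0.05 on the log2 scale and Ahr, the aryl hydrocarbon receptor, dropped by 0.94 ± 0.04. Of 15 genes of bile acid synthesis and transport 11 were lower, 2 higher and 2 not called (camera adjusted p = 0.0265, and adjusted p = 0.191 with an estimated correlation). Acox2, a peroxisomal oxidase, dropped by 1.12 ± 0.05, while Abcb11, the bile salt export pump, went the other way, from 2.37 ± 0.479 to 14.8 ± 1.25 CPM (SD, n = 4 each). The last 2 calls were lost when single libraries were left out. For drug metabolism the camera adjusted p was 0.0569 without Ad-LacZ replicate 2 and 0.0558 without Ad-Pink1 replicate 2. For bile acid genes it was 0.0787 without Ad-LacZ replicate 2, 0.064 without Ad-LacZ replicate 4 and 0.0518 without Ad-Pink1 replicate 4. With total counts as the scaling it was 0.0849 for drug metabolism and 0.0553 for bile acid genes, and with a GC and length correction, chosen after the data were seen, 0.0804 for drug metabolism. The replicate number as a block gave a camera adjusted p of 0.0613 for drug metabolism.

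Of 30 genes of fatty acid oxidation and PPARalpha targets 24 were lower, 4 higher and 2 not called, with a median log2 fold change of -0.44 (camera adjusted p = 0.000179, and adjusted p = 0.191 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, fell from 202 ± 2.45 to 104 ± 4.17 CPM (SD, n = 4 each). Decr1 and Acadl, enzymes of beta-oxidation, dropped by 1.24 ± 0.04 (SE) and 1.01 ± 0.03 on the log2 scale. Of 26 glycolysis genes and HIF1 targets 19 were higher, 4 lower and 3 not called, with a median of 0.59 (camera adjusted p = 0.000521, and adjusted p = 0.376 with an estimated correlation). Pkm, the pyruvate kinase gene, rose from 517 ± 15.7 to 1193 ± 24.2 CPM and the lactate dehydrogenase gene Ldha from 594 ± 14.1 to 1194 ± 28.3 CPM. Egln3, a prolyl hydroxylase of the hypoxia response, rose by 2.55 ± 0.07 on the log2 scale. Of 25 cholesterol synthesis genes and SREBP2 targets 16 were higher, 5 lower and 4 not called (camera adjusted p = 0.0295, and adjusted p = 0.376 with an estimated correlation). Insig1, a sterol sensor partner, rose by 1.25 ± 0.04 on the log2 scale.

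Among 30 integrated stress response genes 25 were higher, 2 lower and 3 not called, with a median log2 fold change of 0.65 (camera adjusted p = 7.31e-07, and adjusted p = 0.138 with an estimated correlation). The serine synthesis gene Phgdh rose from 105 ± 2.58 to 262 ± 5.31 CPM (SD, n = 4 each). Sesn2, a stress-induced regulator of mTORC1, rose by 1.31 ± 0.04 (SE) on the log2 scale and Shmt2, a mitochondrial enzyme of one-carbon metabolism, by 1.06 ± 0.03. Of 22 genes of the endoplasmic reticulum unfolded protein response 18 were higher, 3 lower and 1 not called, with a median of 0.37 (camera adjusted p = 0.00167, and adjusted p = 0.428 with an estimated correlation). The chaperone gene Hspa5 rose by 0.60 ± 0.03, Manf by 0.69 ± 0.04 and Creld2 by 0.84 ± 0.05. Of 19 immediate early genes 14 were lower, 2 higher and 3 not called (camera adjusted p = 0.00637, and adjusted p = 0.138 with an estimated correlation). Egr1 dropped by 2.46 ± 0.06 and Klf6 dropped by 0.85 ± 0.03, while Klf4 and Fosl1 rose by 1.78 ± 0.05 and 1.43 ± 0.05.

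Of 34 type I interferon-stimulated genes 29 were lower and 5 not called, with a median log2 fold change of -1.13 (camera adjusted p = 7.31e-07, and adjusted p = 0.428 with an estimated correlation). The transcription factor genes Irf9 and Stat2 dropped by 0.86 ± 0.05 (SE) and 0.95 ± 0.05, and the RNA sensor gene Ifih1 dropped by 0.84 ± 0.05. Ad-LacZ replicate 2 had the highest values of this list, with a median log2 deviation from each gene's mean of 0.721, against 0.363 to 0.569 in the other Ad-LacZ libraries. Markers of Kupffer cells and macrophages moved the same way: of 21 tested, 17 were lower, 2 higher and 2 not called, with a median of -0.54 (camera adjusted p = 0.00175, and adjusted p = 0.376 with an estimated correlation). Mpeg1 fell from 173 ± 8.73 to 98.6 ± 3.31 CPM (SD, n = 4 each), Cd5l from 87.4 ± 2.14 to 48.4 ± 2.09 CPM and the complement gene C1qb from 48.6 ± 1.36 to 32.3 ± 1.45 CPM, whereas the lysosomal membrane gene Cd68 rose from 28.8 ± 1.39 to 53.6 ± 3.16 CPM.

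Genes of the pathway in which Pink1 acts went both ways. Of 31 tested genes of PINK1-Parkin mitophagy 12 were higher, Pink1 among them, 13 lower and 6 not called (camera adjusted p = 0.81). The median log2 fold change was -0.05, and the mean, which includes Pink1, was 0.24. Parkin itself, listed as Park2 and chosen outside the rule after its values were seen, dropped by 1.5 ± 0.33 (SE) on the log2 scale. It went from 0.829 ± 0.15 CPM in Ad-LacZ to 0.294 ± 0.124 CPM in Ad-Pink1 (SD, n = 4 each). The Ad-Pink1 value is near the level of 3 reads, so the SE may understate counting error. The mitochondrial protease gene Oma1 dropped by 1.11 ± 0.07, and of the mitophagy receptor genes Bnip3 rose by 0.61 ± 0.05 and Bnip3l dropped by 0.43 ± 0.03. Of 32 core autophagy genes 21 were lower, 6 higher and 5 not called, with a median of -0.15 (camera adjusted p = 0.0384, and adjusted p = 0.268 with an estimated correlation). This call was also absent with the pre-ranked form of camera on DESeq2 statistics (camera adjusted p = 0.113). Ulk2 dropped by 0.85 ± 0.04 and Pik3r4 dropped by 0.63 ± 0.05, and Uvrag rose by 0.81 ± 0.04. Of 69 nuclear-encoded genes of oxidative phosphorylation 29 were higher, 21 lower and 19 not called (camera adjusted p = 0.81), where Uqcr10 rose by 1.03 ± 0.04 and Atp5a1 dropped by 0.63 ± 0.03 on the log2 scale. The 34 lysosome genes split into 12 higher, 14 lower and 8 not called (camera adjusted p = 0.81), the 15 genes of the mitochondrial unfolded protein response into 5, 5 and 5 (camera adjusted p = 0.932), and the 54 mitochondrial ribosomal protein genes into 18, 20 and 16 (camera adjusted p = 0.734). Genes encoded in mitochondrial DNA are not among the rows of the table used here.

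**Figure D2:**
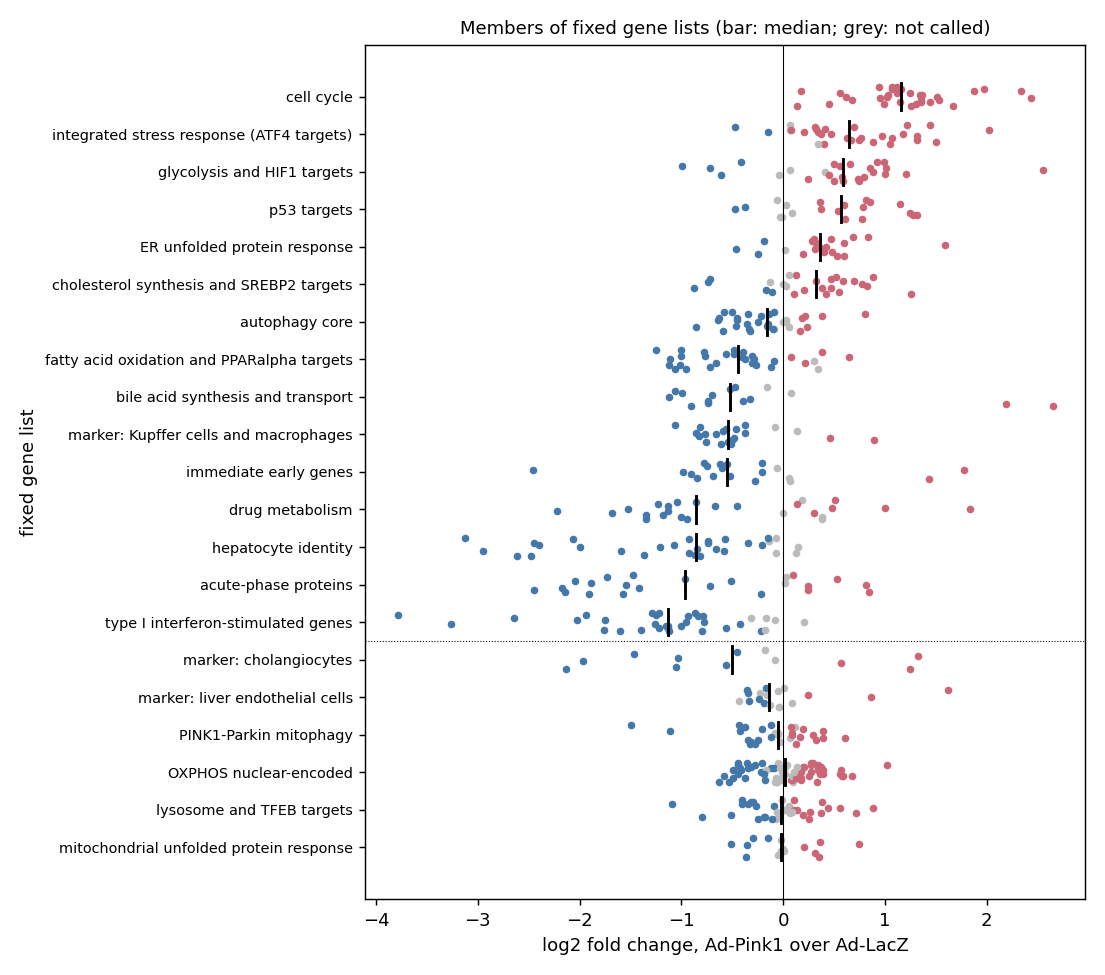
Log2 fold changes (Ad-Pink1 over Ad-LacZ) of the tested members of 15 lists called by camera (above the dotted line) and of 6 lists that were not, leaving out Pink1 as a point. Red points were called higher, blue points called lower and grey points not called by edgeR, and black bars are list medians, from 1.16 for the cell cycle to -1.13 for interferon-stimulated genes above the dotted line.

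**Figure D3:**
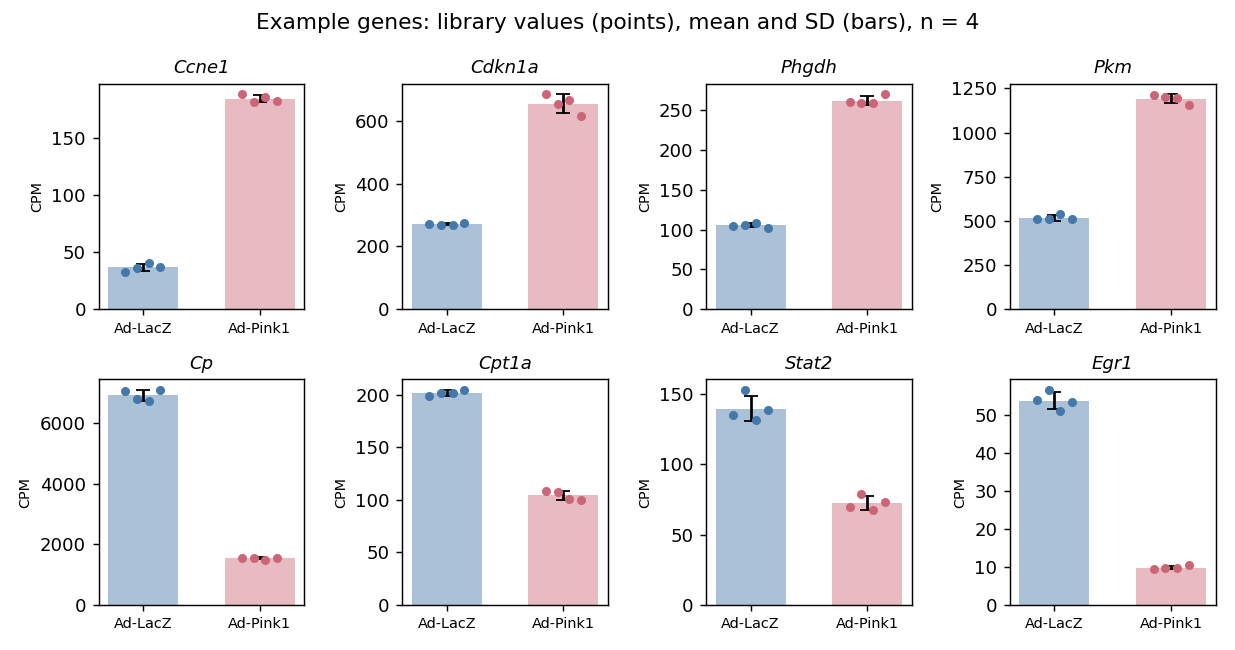
CPM of 8 example genes in the 4 Ad-LacZ and 4 Ad-Pink1 libraries, with points for libraries, bars for means and whiskers for the SD, each axis starting at 0. Ccne1, Cdkn1a, Phgdh and Pkm were higher in Ad-Pink1 and Cp, Cpt1a, Stat2 and Egr1 lower, with no overlap between groups.

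For each of the 15 lists called by camera, the counts adjusted over the list alone were the same as those over all genes tested. None of the 15 calls held when the correlation between genes was estimated from the data. The estimate was below the preset 0.01 for p53 targets (-0.0183), immediate early genes (-0.00545) and bile acid genes (-0.0458). A higher correlation within these lists thus does not account for their lost calls. For the other called lists the estimate was above 0.01, up to 0.631 for interferon-stimulated genes. The test with an estimated correlation also had fewer degrees of freedom, so these lost calls cannot be put down to correlation alone. The specimen numbers (1 to 4 against 26 to 30) and index numbers (1 to 4 against 17 to 20) in the labels divide exactly as the groups do, so a preparation or sequencing batch and the vector cannot be told apart.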

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

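The tests of explanations below were chosen after the data were seen. What each would show was written before its own result for the splits, GC content and length, Pink1 reads assigned elsewhere and the left-out library, and after it for the scaling factor, batch, genomic DNA, the reads outside Pink1 and macrophages.

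Within groups of 4 libraries, 11 of 198 sets of values had a library far from the others by Dixon's test, where chance at 1 in 20 gives about 10. In Ad-LacZ these were Aldh1a3 in replicate 2 (0.6 CPM, others 0.267 to 0.279), Pik3r1 in replicate 4 (246 CPM, others 239 to 240), Aurka in replicate 4 (39.6 CPM, others 43.5 to 43.9), Pkm in replicate 3 (541 CPM, others 508 to 510), Ctsf in replicate 3 (24.3 CPM, others 22.7 to 22.9) and Scd2 in replicate 1 (44.4 CPM, others 46.6 to 46.8). In Ad-Pink1 they were Spp1 in replicate 1 (2430 CPM, others 2370 to 2380), Phgdh in replicate 4 (270 CPM, others 259 to 260), Manf in replicate 2 (120 CPM, others 126), Cd5l in replicate 2 (45.2 CPM, others 49.1 to 49.6) and Aldh1a1 in replicate 3 (1500 CPM, others 1510).

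Most tested genes changed: 9901 of 13095 were called. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many called genes, the real one. The highest of the 34 others gave 0 by edgeR (585 at an unadjusted p under 0.05). Each other split mixes the groups, and the libraries may not be separate animals or cultures. The calls thus follow the real grouping, but a chance difference between cultures cannot be excluded. A single scaling factor, such as Pink1 taking 11.2% of the reads would set, moves every gene by one amount. Past a log2 change of 0.58, however, the smaller side held 1802 genes, and 1822 with total counts as the scaling, which centres no values. This covers changes of that size only. With smaller changes included, the counts depended on the scaling: 4896 higher and 5005 lower with TMM, 4175 and 5849 with total counts. After removal of each library's trend on GC content and length 3953 genes passed a log2 change of 0.58 and the adjusted p, against 3893 before. A library or sequencing batch stays open and cannot be told apart from the vector, since 0 of the Ad-Pink1 libraries had a specimen or index number within the range of Ad-LacZ, and an effect of Pink1 or of viral dose remains open beside it as a hypothesis.

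In 45 untested genes with no read in any Ad-LacZ library and at least 10 pooled reads in Ad-Pink1, Ad-Pink1 held 1162 reads. With 2 tested genes they made 47, of which 35 had reads in all 4 Ad-Pink1 libraries, against 1 gene in the opposite direction. Genomic DNA would raise the reads of olfactory and vomeronasal receptor genes, but their share of the reads outside Pink1 was 0.875 times that in Ad-LacZ. Reads of mouse Pink1 assigned elsewhere are unlikely, since 0 of the 46 genes searched share a 25-base stretch with a mouse Pink1 transcript. Vector sequence and a transgene of another species or form were not searched. The total of reads outside Pink1 differed by a ratio of 1.001. What stays open is transcription at low levels, a batch difference or reads from the sequences not searched. Much of the 1162 reads lay in genes not seen in all 4 Ad-Pink1 libraries, which may reflect the assignment of reads among copies. Examples, chosen after their values were seen, are Eif3j2 (304 reads in 3 libraries), Raet1c (114 in 2), Ndufs5 (70 in 2) and Btg3 (43 in 1).

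Interferon-stimulated genes and macrophage markers were lower together. The difference of their medians was -0.587 (95% bootstrap interval over genes, taken as independent, -0.745 to -0.275), which decides nothing, since macrophages could also supply the interferon that other cells respond to. Fewer macrophages in the Ad-Pink1 cultures thus cannot be told apart from lower expression per cell for either list, and of the 21 markers 2 were higher, Cd68 among them. Ad-LacZ replicate 2, with the highest interferon-stimulated genes, was not the source, since 28 of the 29 genes called lower stayed so without it. A weaker interferon response in Ad-Pink1 cells, or a difference in virus preparation or dose, remains an untested hypothesis.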

How the results depend on the processing

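The GC and length correction was chosen after the data were seen. Of the 15 lists called by camera, 0 passed with a correlation estimated from the data, whereas fry, which does not compare a list with other genes, called 29 lists by direction and 37 in either direction; its directional test put PINK1-Parkin mitophagy higher (adjusted p = 1.35e-05), where camera had it lower and not called, and the mean of that list includes Pink1. Requiring an absolute log2 change of 0.58 as well left 2091 genes higher and 1802 lower by construction. Under the other alternatives the counts stayed within 1.5 times 4896 and 5005. Scaling by total counts gave 4175 higher and 5849 lower and DESeq2 4720 and 4672. Total counts gave 13 lists, no filter 20, limma-voom 18, the GC and length correction 16 (14 of the main 15 among them) and DESeq2 21 (again 14 of the 15). Without a filter, with limma-voom and with DESeq2 statistics, dedifferentiation and fetal liver genes were called (camera adjusted p = 0.0268, 0.0186 and 3.35e-08), as were NF-kB and cytokine genes (camera adjusted p = 0.0494, 0.0398 and 0.0105). Cholangiocyte markers were called with limma-voom and DESeq2 (camera adjusted p = 0.0414 and 3.13e-08). Ketogenesis and TCA cycle genes were called without a filter, with the GC and length correction and with DESeq2 (camera adjusted p = 0.0268, 0.0479 and 0.0223), and NRF2 targets and interferon gamma genes without a filter (camera adjusted p = 0.0421 and 0.0473) and with DESeq2 (camera adjusted p = 0.00139 and 0.0343). Gluconeogenesis genes were called with DESeq2 alone of these (camera adjusted p = 0.0265) and cytosolic ribosomal protein genes with the GC and length correction alone (camera adjusted p = 0.0188). The cause of these differences was not tested, and with DESeq2 the form of the list test differed too. Leaving out single libraries gave 4778 to 4936 higher, 4812 to 5012 lower, 13 to 15 lists and a Pink1 log2 fold change of 10.42 to 10.58. The correlations of deviations between libraries with the same number ran from -0.033 to 0.13. Of the 4 Ad-LacZ libraries 2 correlated best with their own number. With 4 libraries per group this does not settle whether the numbers pair the samples. With the replicate number as a block 4943 genes were higher, 5063 lower, 14 lists called, without drug metabolism (camera adjusted p = 0.0613), and the Pink1 log2 fold change was 10.48; no other call of a list or named gene changed. The other 157 genes named by the rule were picked from these data by fold or adjusted p, so few calls could be lost. They kept their direction and their call in 2983 of 2983 combinations of gene and alternative. Lists counted as unchanged in 721 of 777, with 25 calls lost, 30 gained and 1 reversed. A list called in neither fit counted as unchanged even if its direction differed. Leaving out the robust option could not change a list, since camera used log-CPM. Depth limits genes near 0.143 to 0.18 CPM, the level of 3 reads.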

Other observations

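Several fixed lists did not pass camera although most of their members were called, but 75.6% of all tested genes were called too. Of 31 NRF2 targets and antioxidant genes 17 were lower (18 adjusted over the list alone), 9 higher and 5 not called (camera adjusted p = 0.127), with the glutathione synthesis gene Gclc lower (835 ± 25.3 to 356 ± 16.9 CPM; SD, n = 4 each) and catalase, Cat, going from 1320 ± 27.5 to 664 ± 14.3 CPM. Of 22 ketogenesis and TCA cycle genes 13 were lower, 6 higher and 3 not called (camera adjusted p = 0.0884). The pyruvate carboxylase gene Pcx rose from 77.1 ± 2.21 to 134 ± 2.6 CPM. Of 28 apoptosis and necroptosis genes 15 were higher, 9 lower and 4 not called (camera adjusted p = 0.218), with Bax higher by 0.60 on the log2 scale and Bmf going from 43.4 ± 1.49 to 17.8 ± 2.55 CPM. Of 24 genes of fatty acid and triglyceride synthesis 15 were higher, 8 lower and 1 not called (camera adjusted p = 0.231), and Scd2 rose from 46.1 ± 1.15 to 92.5 ± 3.73 CPM while Cd36 fell from 191 ± 4.99 to 97.4 ± 3.8 CPM. Of 23 urea cycle and amino acid genes 11 were higher, 9 lower and 3 not called (camera adjusted p = 0.81), with the tyrosine aminotransferase gene Tat from 24.4 ± 1.02 to 4.19 ± 0.388 CPM and Got1 from 57.0 ± 1.48 to 121 ± 3.4 CPM. Of 19 genes of gluconeogenesis and insulin signalling, Tat among them, 8 were lower, 4 higher and 7 not called (camera adjusted p = 0.274).

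Of 29 interferon gamma and antigen presentation genes 17 were lower, 9 higher (10 adjusted over the list alone) and 3 not called (camera adjusted p = 0.127). Gbp2 fell from 27.5 ± 2.4 to 6.98 ± 0.516 CPM (SD, n = 4 each) while the class I gene H2-Q7, one of several near-identical copies and overlapping H2-Q9 on the same strand, rose from 58.9 ± 4.89 to 213 ± 8.24 CPM. Of 24 NF-kB and cytokine genes 15 were lower, 7 higher and 2 not called (camera adjusted p = 0.0933). Of 25 dedifferentiation and fetal liver genes 15 were lower, 8 higher and 2 not called (camera adjusted p = 0.0633), and Sox9 fell from 70.4 ± 2.96 to 25.5 ± 0.946 CPM. Cholangiocyte markers, which share Sox9, Spp1 and Krt19 with that list, were 7 lower, 3 higher and 2 not called of 12 (camera adjusted p = 0.0899). The 18 liver endothelial markers were 3 higher, 6 lower (5 adjusted over the list alone) and 9 not called (camera adjusted p = 0.519), and the 12 stellate cell markers 3 higher, 3 lower and 6 not called (camera adjusted p = 0.831). In both lists the mean was above 0 and the median below it. Of 20 genes of mitochondrial biogenesis 7 were higher, 8 lower and 5 not called (camera adjusted p = 0.952), with Tfam higher by 0.71 on the log2 scale. The median of that list was below 0 and its test pointed up, and for the mitochondrial unfolded protein response the median was below 0 and the mean above. Fission and fusion genes were 7 higher, 8 lower and 2 not called (camera adjusted p = 0.563), heat shock genes 5, 8 and 3 (camera adjusted p = 0.598), collagen and matrix genes 10, 7 and 8 (camera adjusted p = 0.667) and cytosolic ribosomal protein genes 14, 24 (22 adjusted over the list alone) and 28 (camera adjusted p = 0.511). Adjusted over the list alone, oxidative phosphorylation had 28 genes higher and lysosome genes 15 lower. No lymphocyte or neutrophil marker passed the filter, and of the red blood cell markers 1 did and was not called.

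In the Ad-LacZ cells the gene with the most reads in the table, uncorrected for transcript length, was Clu, which encodes clusterin, with 34870 ± 822 CPM (SD, n = 4), while albumin, Alb, had 2230 ± 27.1 CPM. In Ad-Pink1 Clu had 18540 ± 641 CPM and Alb 1753 ± 31.0 CPM. These 2 genes were chosen after their values were seen.

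In the authors' deposited table an adjusted p under 0.05 was given for 9356 of 17653 genes, 4659 higher and 4697 lower. Of the 9901 genes called here, 8833 were also called in that table in the same direction, 0 in the opposite direction and 1068 not called there.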
